A study of Mus musculus with 2 samples.

How the data were processed

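Gene expression was measured in single cells of small intestine from naive Rorc WT and Rorc delta369 mice, with 1 library per genotype. Per the labels' protocols, tissue was dissociated to a suspension, cells were captured in a microwell chip with barcoded beads that bind poly(A) RNA, and libraries were sequenced in pairs of reads on an Illumina NovaSeq instrument. The deposited values were raw UMI counts per gene and cell barcode, made by the authors with STAR 2.6.1a and featureCounts 2.0.1 on GRCm38 (mm10) per the submitters' processing notes, which do not give the role or order of each tool. The filter that chose the deposited barcodes was not given in the sources used here, and the lowest barcode total was 500 UMIs in Rorc WT and 557 in Rorc delta369. The design text mentions 3 littermates per group, and whether the cells of a library came from 1 animal or from a pool was not given in the sources used here. Gene identifiers were matched to GENCODE release M21, with 32445 of 32589 found and 144 not.

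Barcodes were kept with at least 500 UMIs and 200 detected genes and at most 20% mitochondrial UMIs. The first 2 limits removed 388 Rorc WT and 234 Rorc delta369 barcodes, and the mitochondrial limit 1253 and 1461. Doublets were scored in each library with Scrublet in scanpy 1.11.5, with 30 components and exact neighbours, and barcodes above a common score of 0.25 were removed, 237 in Rorc WT and 338 in Rorc delta369. Automatic thresholds were 0.254 and 0.210 and would have marked 243 and 462 barcodes. Cells with over 10% haemoglobin UMIs were set aside as erythroid-like, 11 in Rorc WT and 17 in Rorc delta369. This left 13801 cells with 58402234 UMIs in Rorc WT and 16871 cells with 66241451 UMIs in Rorc delta369, erythroid-like cells included.

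Both libraries were clustered together without batch correction. Counts were scaled to 10000 per cell and logged, 2500 variable genes chosen across both libraries among genes seen in at least 10 cells were scaled with a limit of 10, and 40 principal components and 20 nearest neighbours were used. Edges with a shared-neighbour weight above 1 in 15 entered Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 1.0. Clusters were assigned to a compartment by their highest marker score and clustered again within it, with 2000 genes, 30 components, 15 neighbours and resolutions of 1.2 for T cells and ILCs, 0.6 for B cells and plasma cells, 0.8 for epithelium and 1.0 for myeloid and stromal cells. Rorc and the other genes of the RORγt programme were kept out of clustering and naming, as were sex-linked, mitochondrial, ribosomal protein and haemoglobin genes and antigen receptor segments in clustering.

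A cluster was named after the class whose markers scored highest, as the mean deviation of log2 CPM (with an offset of 20) from the other clusters. It needed at least 10 cells, at least 3 markers detected in 5% of its cells, a score over 0.5, no other class of its compartment above 0.85 of that score, none of another compartment above 0.6 of it, and no other class with more markers among its 10 leading genes. Shallow clusters without a leading marker also stayed unnamed. Named classes are written as B-like, ILC3-like and so on, since no sorting or protein measure stood behind them. Cells in unnamed clusters came to 2107 in Rorc WT (15.3%) and 2925 in Rorc delta369 (17.3%). They were kept in all totals, and 7 unnamed clusters with at least 50 cells in each library were compared like the 11 named classes of that size.

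With 1 library per genotype no test was run. Counts were summed over the cells of a class in each library and given as counts-per-million (CPM) of all UMIs of the class. Exact 95% intervals (Poisson for levels, Clopper-Pearson for shares, conditional binomial for ratios) cover counting error only, not the spread between animals, and UMIs of 1 cell are not independent of each other. A count of 0 was bounded by a floor of 3 UMIs over the class, and a share of 0 by 3 cells of the class, which is not an exact interval. For Rorc, cells were also thinned to 1000 UMIs. Of 26 gene lists with 362 genes, 355 genes were found. A list's median log2 ratio used members with at least 10 UMIs over both libraries in the class, a library under 3 UMIs being set to 3, and was set beside 10000 random lists of as many genes drawn from 20 bins of expression. Its interval came from 200 Poisson redraws of the counts. Genes were ranked and named by ratio, a library under 3 UMIs being set to 3, so that the order can differ from that of the ratios printed, among those with at least 30 UMIs and 50 CPM in the higher library, at a level of at least 10% of that in the class where that library had its highest level, with the first 10 each way given in ILC3-like and enterocyte-like cells and the first 5 each way in other classes. Mitochondrial, ribosomal protein, haemoglobin and sex-linked genes, receptor variable segments and unnamed gene models were left out of that ranking.

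The comparisons, gene lists, markers, naming rule for genes, filters and most alternatives were fixed before the data were examined. Set afterwards were the common doublet score, the haemoglobin limit, the smallest cluster size, the limits on mixed clusters, the choice of which list medians are described, the thresholds for results singled out for a closer look, and the alternatives named as added. The alternatives covered stricter and looser filters, doublets, resolution, scaling, abundant genes, thinning, free RNA, floors, class borders and class shares. The steps from summed counts to ratios were tested on simulated data, in which counts of both genotypes were drawn from the mixed profile of a class at the observed depths and 200 genes per class were given a known ratio. Analyses used python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and scikit-learn 1.9.0, and matplotlib 3.10.9 for figures. The sequence of the allele and raw reads were not used here.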

Results

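Single-cell RNA sequencing was carried out on small intestine of naive mice at 20 weeks of age. A piece of about 0.5 cm, taken about 10 cm from the cecum, was dissociated and loaded on a microwell chip with barcoded poly(A) capture beads. The labels give 1 library from Rorc WT tissue and 1 library from tissue with the Rorc delta369 allele. Rorc encodes RORγt, the transcription factor that defines the innate lymphoid cells called ILC3s and Th17 cells, and the series concerns a regulatory element through which ILC3s raise RORγt. The Rorc WT library held 15679 barcodes with 61572127 UMIs, at a median of 1778 UMIs per barcode. The Rorc delta369 library held 18904 barcodes with 69823234 UMIs, at a median of 1741. After filtering, 13801 and 16871 cells were left, with medians of 1866 and 1801 UMIs. Both libraries carried the female-specific transcript Xist, at 192 counts-per-million (CPM, UMIs relative to all UMIs of the cells summed) in Rorc WT and 201 CPM in Rorc delta369, and the Y-linked gene Ddx3y at 0.103 and 0.151 CPM. With 1 library per genotype no difference between them had a replicate check, and all intervals are 95% intervals that cover counting error only, from Poisson redraws of the counts for list medians and exact for the rest. Ratios are given as Rorc delta369 over Rorc WT.

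The first comparison asked whether Rorc transcripts differed in ILC3s, the cells for which the series reports the element. In ILC3-like cells Rorc stood at 622 CPM in Rorc WT (80 UMIs, 95% interval 493 to 774) and at 430 CPM in Rorc delta369 (34 UMIs, 298 to 601). The ratio was 0.691, with an interval of 0.448 to 1.04 that included 1. A Rorc UMI was found in 52.8% of 72 ILC3-like cells of Rorc WT (exact binomial interval 40.7% to 64.7%) and in 43.1% of 51 cells of Rorc delta369 (29.3% to 57.8%). After each cell was thinned to 1000 UMIs, these shares were 45.9% of 61 cells (33.1% to 59.2%) and 27.3% of 44 cells (14.96% to 42.8%). As background, a Rorc UMI was present in 0.588% and 1.35% of B-like cells (median depth 1258 and 1429 UMIs) and in 0.601% and 0.636% of intraepithelial T-like cells (1930 and 1890.5 UMIs), against median depths of 1570 and 1429 UMIs in ILC3-like cells. Summed over all T-like and ILC-like cells, Rorc was lower in Rorc delta369, at 15.1 CPM in Rorc WT and 8.11 CPM in Rorc delta369 (ratio 0.538, 0.404 to 0.715), a sum that also takes in the lower share of ILC3-like cells.

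Epithelial cells carried most Rorc UMIs of both libraries, 87.9% in Rorc WT and 93.8% in Rorc delta369. In enterocyte-like cells Rorc stood at 42.1 and 44.9 CPM (858 and 1059 UMIs, ratio 1.07, 0.973 to 1.17), and in tuft-like cells at 33.3 and 39.0 CPM (1.17, 0.781 to 1.75). The ratio was 1.17 in goblet-like, 0.961 in stem-like or transit-amplifying-like, 1.28 in Paneth-like and 1.01 in enteroendocrine-like cells, with intervals that included 1. T-like cells held 10 and 5 Rorc UMIs (25.9 and 38.5 CPM, ratio 1.49, 0.399 to 4.78), and intraepithelial T-like cells 21 and 31 UMIs (2.99 and 3.41 CPM). B-like cells held 8 and 2 UMIs, macrophage-like cells 1 and 2, and plasma-like cells 0 and 0. Over all filtered cells Rorc stood at 22.4 and 23.7 CPM (1.06, 0.982 to 1.14). Rorc (ENSMUSG00000028150) is a protein-coding gene on the plus strand of chromosome 3, from 94372794 to 94398276 in GRCm38. The altered element is regulatory, so transcript counts of Rorc did not check the deletion itself. Counts were made per gene, so they do not tell the RORγt transcript from other transcripts of Rorc, in epithelial cells or elsewhere.

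**Figure D1:**
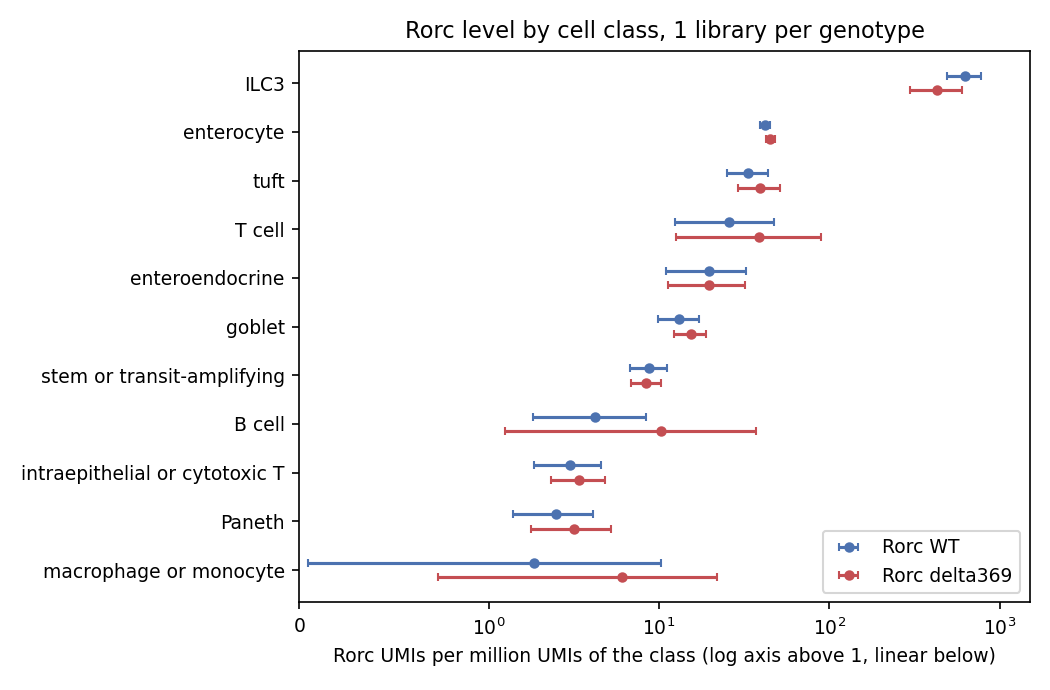
Rorc level in each cell class as counts-per-million (CPM) on a log axis, with 1 point per library (Rorc WT and Rorc delta369) and exact 95% Poisson intervals for counting error. ILC3-like cells stood at 622 CPM in Rorc WT and 430 CPM in Rorc delta369, and enterocyte-like cells at 42.1 and 44.9 CPM.

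ILC3s are lymphocytes of the mucosa that respond to IL-23 and IL-1β and act on the epithelium through IL-22. ILC3-like cells, a single cluster led by Il7r, Cxcr6, Ltb, Emb and Tmem176a, made up 0.522% of Rorc WT cells (72 cells, 0.408% to 0.657%) and 0.302% of Rorc delta369 cells (51 cells, 0.225% to 0.397%). The ratio was 0.579 (0.397 to 0.841) over all cells, 0.544 (0.373 to 0.790) over T-like and ILC-like cells, and 0.759 (0.520 to 1.10) over immune cells. The cytokine Il22 was found as 17 UMIs in 4 of 72 Rorc WT cells, and as 0 UMIs in 51 Rorc delta369 cells, which by the floor of 3 cells allows a share of up to 5.88% of cells with a UMI (6.98% by the exact interval), beside 0 UMIs in B-like cells of both libraries and a UMI in 0.120% and 0.0454% of intraepithelial T-like cells. Receptor genes went both ways. With counting intervals that left out 1, the IL-1 receptor Il1r1 (22 and 5 UMIs, ratio 0.369, 0.109 to 0.9998) and the oxysterol receptor Gpr183 (74 and 27 UMIs, 0.593, 0.367 to 0.933) were lower in Rorc delta369, and the IL-17 receptor subunit Il17re (6 and 11 UMIs, 2.98, 1.01 to 9.81) and the activating receptor Ncr1 (36 and 37 UMIs, 1.67, 1.03 to 2.72) were higher. These intervals treat UMIs as independent, which UMIs of 1 cell are not, and those of Il1r1, Il17re and Ncr1 ended close to 1. Within counting error lay the IL-23 receptor Il23r (29 and 11 UMIs, 0.617, 0.278 to 1.27), Ccr6 (0.985), Il2ra (1.15) and Cxcr6 (1.22).

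Over the RORγt programme list, 15 members were measured in ILC3-like cells, of which 8 were higher and 7 lower in Rorc delta369, with a median log2 ratio of 0.03 (counting interval -0.19 to 0.21). The median lay at percentile 50.9 of 10000 random lists matched on expression. Among the higher members were also the transporter Slc6a20a (28 and 36 UMIs, 2.09, 1.24 to 3.56) and Tmem176b (1.19, 1.01 to 1.41). The lymphotoxin gene Ltb (1.02) differed less than counting error. The type 1 programme, with genes of interferon-γ-producing lymphocytes, had 5 members higher and 5 lower, at a median of -0.07. By the fixed naming rule the genes with the highest ratios were Fabp6, Fos, Ahnak, Ralbp1, Ggnbp2, Dynlrb1, Cyb5a, Cd47, Slc6a20a and Gimap9. Fos, an immediate-early transcription factor gene, counted 41 and 85 UMIs (3.37, 2.30 to 5.02), and Fabp6, which encodes the ileal bile acid-binding protein of enterocytes, 4 and 93 UMIs, of which 58 lay in 1 cell. The genes with the lowest ratios were Clca4b, Trdc, Trgc2, Abi3, Psma4, Ssr4, Cast, Bclaf1, Epcam and Guca2b, from 0.143 to 0.425. Single cells held 45 of 57 Clca4b UMIs, 15 of 42 Trdc UMIs, 16 of 32 Trgc2 UMIs (log2 ratio 0.056 after thinning), 23 of 43 Epcam UMIs and 45 of 65 Guca2b UMIs in Rorc WT. With the stricter filter of 1000 UMIs and 10% mitochondrial UMIs, 21 and 18 ILC3-like cells were left and the median of the RORγt programme was -0.63.

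The second comparison asked how the make-up of the tissue differed. B-like cells were the class with the widest gap, at 9.85% of Rorc WT cells (1360 cells, 9.36% to 10.4%) and 0.439% of Rorc delta369 cells (74 cells, 0.345% to 0.550%), a share 22.5 times larger in Rorc WT. Macrophage-like or monocyte-like cells made up 1.79% and 0.854% (ratio 0.477, 0.386 to 0.588), dendritic-like cells 0.312% and 0.113% (0.361, 0.199 to 0.634), plasma-like cells 0.485% and 0.279% (0.574, 0.387 to 0.846) and mesothelial-like cells 0.428% and 0.0889% (0.208). Enterocyte-like cells took a larger share in Rorc delta369, 37.8% against 28.7% (1.31, 1.26 to 1.37), as did stem-like or transit-amplifying-like cells, 4.52% against 3.49% (1.29, 1.15 to 1.45). Intraepithelial or cytotoxic T-like cells made up 24.1% and 26.1% (1.08, 1.03 to 1.13).

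Among epithelial cells alone, Paneth-like cells, which secrete antimicrobial peptides at the crypt base, made up 9.78% in Rorc WT and 6.54% in Rorc delta369 (0.669, 0.603 to 0.742), and tuft-like cells, chemosensory cells that make IL-25, 2.98% and 1.98% (0.663, 0.548 to 0.801). The ratio there was 1.09 for enterocyte-like, 1.07 for stem-like or transit-amplifying-like, 0.871 for goblet-like and 0.830 for enteroendocrine-like cells. T-like cells made up 1.53% and 0.456% of all cells (0.299, 0.227 to 0.389), but an unnamed T cell cluster of 161 and 347 cells lay beside them, and with it the ratio was 0.932. Cells in clusters without a name made up 15.3% and 17.3%. Shares also depend on dissociation and on how much of a follicle or of the outer wall a piece holds, for which the labels give no measure.

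**Figure D2:**
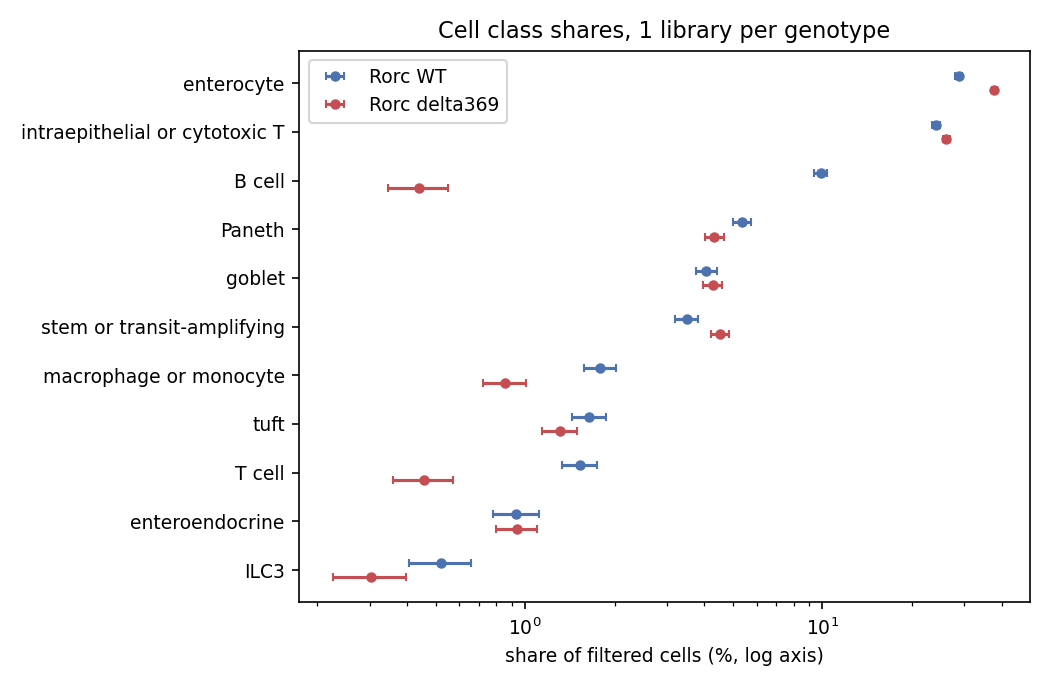
Share of each cell class among all filtered cells, in percent on a log axis, with 1 point per library (Rorc WT and Rorc delta369) and exact 95% binomial intervals for counting error. B-like cells stood at 9.85% in Rorc WT and 0.439% in Rorc delta369, and intraepithelial T-like cells at 24.1% and 26.1%.

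A few B-like barcodes of Rorc delta369 carried most of the plasma cell transcripts of the class. In Rorc WT, 928 of 1360 lay in the largest B-like cluster, with 29 of 74 there in Rorc delta369, where 30 cells lay in the cluster led by Jchain and Igha, against 183 in Rorc WT. Igha, the heavy chain of IgA, counted 652 and 18832 UMIs in the class, of which 7427 lay in 1 cell, and Jchain, which joins IgA into polymers, 99 and 5412 UMIs, of which 1551 lay in 1 cell. In the cluster led by Jchain and Igha, 15 cells of Rorc delta369 held 18745 Igha UMIs and 7 held 5400 Jchain UMIs, against 75 and 7 UMIs in all its cells of Rorc WT. These UMIs add to the 195320 of the class in Rorc delta369, which lowers the ratios of its other genes. By the naming rule these had the highest ratios, followed by the granule protein gene Prg2, at least 119-fold higher (0 and 37 UMIs, against a floor of 3 UMIs over the class) from 4 cells, Ly6c2 (17 and 49 UMIs, 26 of them in 1 cell) and the interferon-induced gene Ifitm3 (40 and 82 UMIs, 80 of them in 1 cell). Those ranked lowest, with counts under 3 UMIs set to 3 for the ranking, were Cnot2 (161 and 2 UMIs, 0.120, 0.0144 to 0.441), Kctd14 (0.134, 0.0160 to 0.491), Parvg (0.184, 0.0375 to 0.547), Rasa2 (0.190) and Tec (0.196). The 10 genes of the MHC class II list had a median log2 ratio of -0.87 in B-like cells, with 9 lower. An unnamed cluster closest to germinal-centre B cells, led by Ms4a1, Ighg1 and Pclaf, held 81 Rorc WT cells and 3 Rorc delta369 cells, and Aicda, the deaminase of class switching, counted 143 and 4 UMIs there.

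The third comparison asked how epithelial cells, the main targets of ILC3 cytokines, differed in gene expression. MHC class II genes, which present peptides to CD4 T cells, were higher in Rorc delta369 in enterocyte-like, stem-like, goblet-like, Paneth-like and tuft-like cells. In enterocyte-like cells 7 of 10 measured genes were higher, with a median log2 ratio of 0.58 (0.54 to 0.62, percentile 100 of random lists). H2-Aa stood at 849 and 1490 CPM (1.75, 1.72 to 1.79), H2-Ab1 at 1235 and 2122 CPM (1.72, 1.69 to 1.74), and Ciita, the master activator of the class, at 13.1 and 32.5 CPM (2.47, 2.15 to 2.85). The lower members were H2-DMb2 (60 and 8 UMIs), H2-Oa (24 and 2) and H2-Ob (41 and 8), genes best known from B cells. In stem-like or transit-amplifying-like cells the median was 0.89 (0.82 to 0.996), with 7 of 8 genes higher, H2-Aa at a ratio of 2.45 and H2-Ab1 at 2.33. The medians were 0.80 in goblet-like, 1.09 in Paneth-like, 0.82 in tuft-like and 0.07 in enteroendocrine-like cells, in which 4 genes were higher and 4 lower. Over the whole library the median was -0.10, in a sum that also held the B-like and myeloid-like cells.

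Genes that interferon-γ induces were higher as well in stem-like or transit-amplifying-like cells, where 15 of 15 measured genes were higher, at a median of 0.54 (0.48 to 0.95). The GTPase gene Iigp1 counted 50 and 252 UMIs (3.40, 2.50 to 4.70) and the ubiquitin-like gene Ubd 24 and 135 UMIs (3.79, 2.45 to 6.13). In enterocyte-like cells 11 of 16 were higher (median 0.26), in goblet-like cells 11 of 14 (0.34), in Paneth-like cells 7 of 12 (0.31), in tuft-like cells 6 of 12 (0.03) and in enteroendocrine-like cells 8 of 10 (0.95). MHC class I genes were higher for 12 of 12 members in stem-like (0.42), goblet-like (0.32) and Paneth-like cells (0.56), for 8 of 12 in enterocyte-like cells (0.20) and for 10 of 12 in tuft-like cells (0.23), and lower for 9 of 12 in enteroendocrine-like cells (-0.18, but 0.30 with the stricter filter and 0.028 to 0.30 with looser filters or other resolutions). Markers of intraepithelial T cells were higher in the same barcodes, for 13 of 13 genes in stem-like (1.01, 0.85 to 1.13), goblet-like (0.86, 0.69 to 1.04) and enterocyte-like cells (0.67, 0.57 to 0.77), and the part of such RNA in the interferon-γ and MHC class I lists was not tested. Genes of cytotoxic lymphocytes were also higher in enterocyte-like cells, at a median of 0.80 over 16 measured members of the type 1 programme.

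Defence genes that IL-22 induces in epithelium were lower in enterocyte-like cells of Rorc delta369. Of 16 measured members 13 were lower, with a median log2 ratio of -0.65 (-0.67 to -0.37), below the central 95% of random lists (-0.07 to 0.17). The acute-phase gene Saa1 counted 1375 and 242 UMIs (0.152, 0.132 to 0.174). The antimicrobial lectin genes Reg3b and Reg3g stood at ratios of 0.540 (0.538 to 0.542) and 0.764 (0.759 to 0.769), and the nitric oxide synthase gene Nos2 at 0.547 (0.497 to 0.602). The alarmin gene S100a8 counted 34 and 0 UMIs, and 0 in 6369 cells allows, by the floor of 3 cells, a share of up to 0.0471% of cells with a UMI. S100a8 is also a neutrophil marker. Free RNA of myeloid cells, whose share was smaller in Rorc delta369 (ratio 0.514), was not excluded as the source of its UMIs. Reg3b was also lower in stem-like (0.506), goblet-like (0.712), Paneth-like (0.614), tuft-like (0.522) and enteroendocrine-like cells (0.377), and the medians of the list there were -0.20, -0.25, -0.12, -0.41 and -0.70, the last being 0.22 with the stricter filter and 0.11 after thinning. In enterocyte-like cells the median was -0.32 and the ratios of Saa1 and Nos2 were 0.235 and 0.886 with cluster shares within the class held at those of Rorc WT, a setting added after the values were seen. Reg3b UMIs were also found in intraepithelial T-like (6327 and 6905 UMIs, 0.843), T-like (0.879) and macrophage-like cells (0.879). Free RNA of enterocytes thus stays open as a part of the Reg3b ratios outside enterocyte-like cells.

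**Figure D3:**
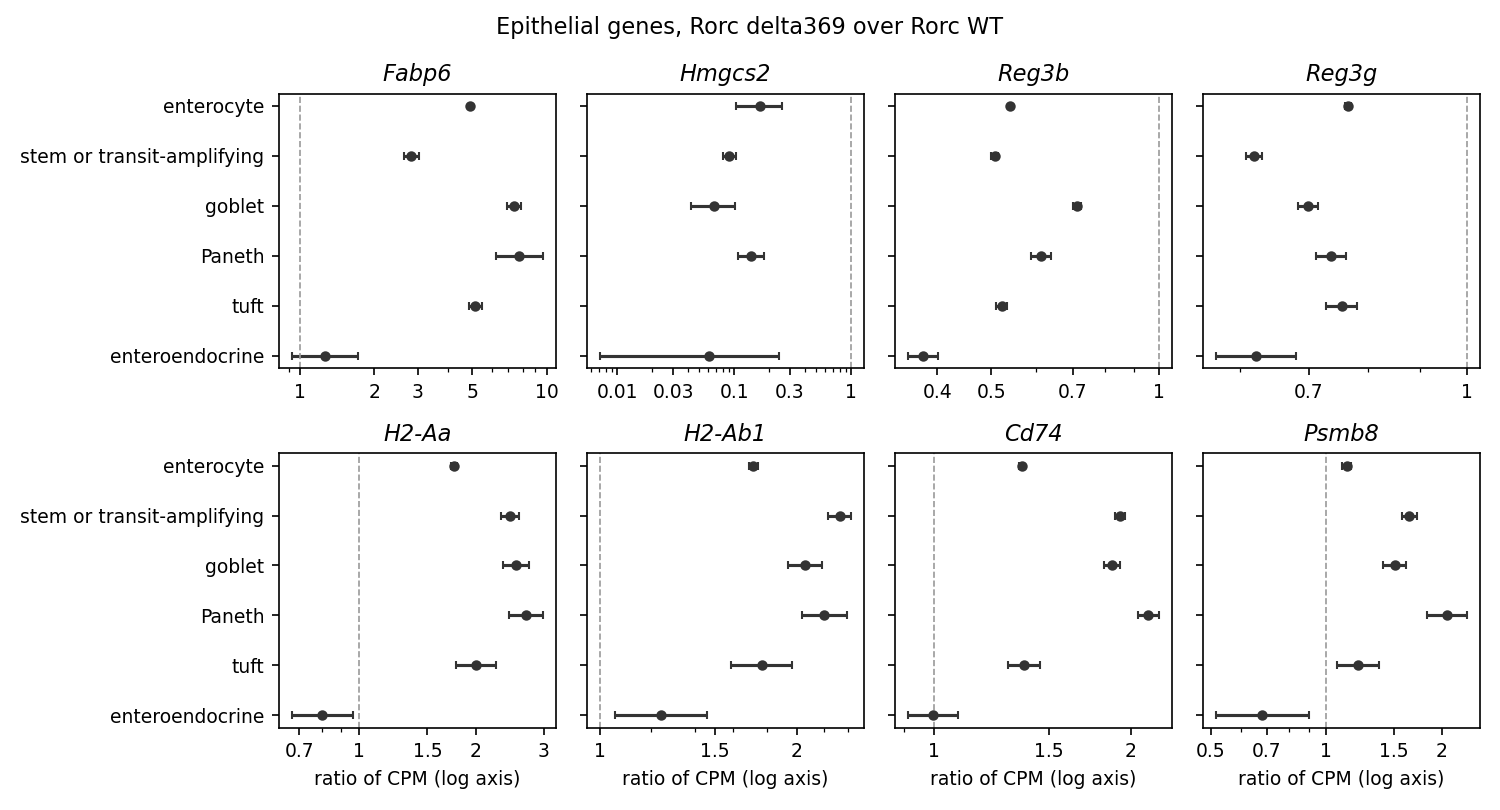
Ratio of CPM, Rorc delta369 over Rorc WT, on a log axis for named genes in 6 epithelial classes, with exact 95% intervals for counting error and a line at 1. Reg3b lay below 1 in each class shown (0.377 to 0.712), while H2-Aa lay above 1 in 5 classes and at 0.802 in enteroendocrine-like cells.

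Paneth-like cells of Rorc delta369 had lower levels of several antimicrobial genes. Of 14 measured genes of the Paneth list 12 were lower, at a median of -0.30 (-0.32 to -0.20) against a median of 0.18 over all genes of the class. The α-defensin genes Defa22 and Defa21 stood at 0.402 (0.399 to 0.405) and 0.466 (0.463 to 0.470), the lysozyme gene Lyz1 at 0.733 and Defa24, the most abundant of those named, at 0.960. Defensin paralogs share reads, so the split between members is uncertain, and the median was -0.07 with cells thinned to 1000 UMIs. By the naming rule Psmb8 (2.06), Psmb9, Rnase1, Srsf11 and Glod5 had the highest ratios, and Hmgcs2 (0.140), Defa22, Defa35, Defa41 and Defa21 the lowest.

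Fabp6 and Hmgcs2 differed between the libraries in most epithelial classes. Fabp6, the ileal bile acid-binding protein, had the highest ratio in enterocyte-like cells, at 1344 CPM in Rorc WT and 6572 CPM in Rorc delta369 (4.89, 4.83 to 4.95), and was found in 20.5% and 37.4% of cells (median depth 2180 and 1588 UMIs). Its ratio was 7.37 in goblet-like, 7.72 in Paneth-like, 5.15 in tuft-like, 2.83 in stem-like and 1.26 in enteroendocrine-like cells. Fabp6 UMIs were also found in intraepithelial T-like cells, which are not known to make it, in 5.35% and 22.0% of cells (median depth 1930 and 1890.5 UMIs, ratio of levels 5.22). Its ratio was also 5.44 in T-like cells (23 and 42 UMIs) and 3.04 in macrophage-like cells (38 and 70 UMIs). Free RNA of enterocytes thus stays open as a part of the ratios outside enterocyte-like cells. Other members of the bile acid and ileal transport list did not follow, with a median of -0.08 in enterocyte-like cells (5 higher, 7 lower, but 0.016 with the stricter filter and 0.12 at the cluster shares of Rorc WT) and the bile acid importer Slc10a2 at 0.788. Hmgcs2, the rate-limiting enzyme of ketone body synthesis, was lower in stem-like or transit-amplifying-like cells, with 2007 and 271 UMIs (0.0911, 0.0799 to 0.103), and in Paneth-like (0.140), goblet-like (0.0671) and enterocyte-like cells (129 and 25 UMIs, 0.167). Intraepithelial T-like cells also held 43 and 3 Hmgcs2 UMIs (0.0539). In Rorc WT these were 43 of 7020706 UMIs, much the same level as 129 of 20381845 in enterocyte-like cells. Free RNA thus stays open as the source of Hmgcs2 in enterocyte-like cells. The fatty acid oxidation genes Acot1 (0.374), Acadl (0.508) and Acaa2 (0.571) were among the lowest in stem-like cells, with Reg3b.

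In enterocyte-like cells the naming rule gave, after Fabp6, the gasdermin gene Gsdmc4 (4.75, 4.11 to 5.52), the acyl-CoA synthetase gene Acsl3 (3.85, 3.48 to 4.27), the glutathione transferase genes Gstm1 (2.62) and Gsta1 (2.12), the apolipoprotein genes Apol9b (2.32) and Apol9a (2.04), the sialic acid transporter gene Slc17a5 (2.26), the lamin gene Lmna (2.03) and the ectonucleotidase gene Nt5e (2.02). The lowest were Saa1, the mannose-binding lectin gene Mbl2 (0.175), the pyruvate dehydrogenase kinase gene Pdk4 (0.451), the glucose-6-phosphatase gene G6pc (0.475), Sgk1 (0.520), Dnase1 (0.525), Reg3b, Nos2, the phosphate transporter gene Slc34a2 (0.552) and Sprr2a3 (0.553). The fat absorption list had 7 members higher and 9 lower (-0.05, but 0.030 after thinning), and the carbohydrate and peptide digestion list 4 higher and 11 lower (-0.14, but 0.047 at the cluster shares of Rorc WT). The largest enterocyte-like cluster, led by Apoa4, held 974 of 3963 cells in Rorc WT and 2296 of 6369 in Rorc delta369. At the cluster shares of Rorc WT, the ratio of Fabp6 was 4.64 and that of Gsdmc4 3.62.

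Stem-like or transit-amplifying-like cells of Rorc delta369 also had more of the heat shock genes Hspa1a (115 and 869 UMIs, 5.10, 4.19 to 6.25) and Hspa1b (4.94, 4.08 to 6.04), followed by H2-DMb1 (1.79), Psmb8 (1.65) and H2-DMa (1.63). The list of dissociation and immediate-early stress genes was higher there for 16 of 18 members, at a median of 0.34. Goblet-like cells, which make mucus, had the highest ratios after Fabp6 for Ifit1bl1 (2.33, with 157 of 311 UMIs in 1 cell), Cyp3a11 (2.03), Gstm3 (1.86) and Hsph1 (1.85), and the lowest after Hmgcs2 for Slc34a2 (0.494), Reg1 (0.516, with 128 of 315 Rorc WT UMIs in 1 cell and a log2 ratio of 0.10 after thinning), Fosb (0.557) and Zfp467 (0.573). The goblet mucus list was lower for 9 of 11 members in these cells, at a median of -0.12, but 0.021 at the cluster shares of Rorc WT.

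**Figure D4:**
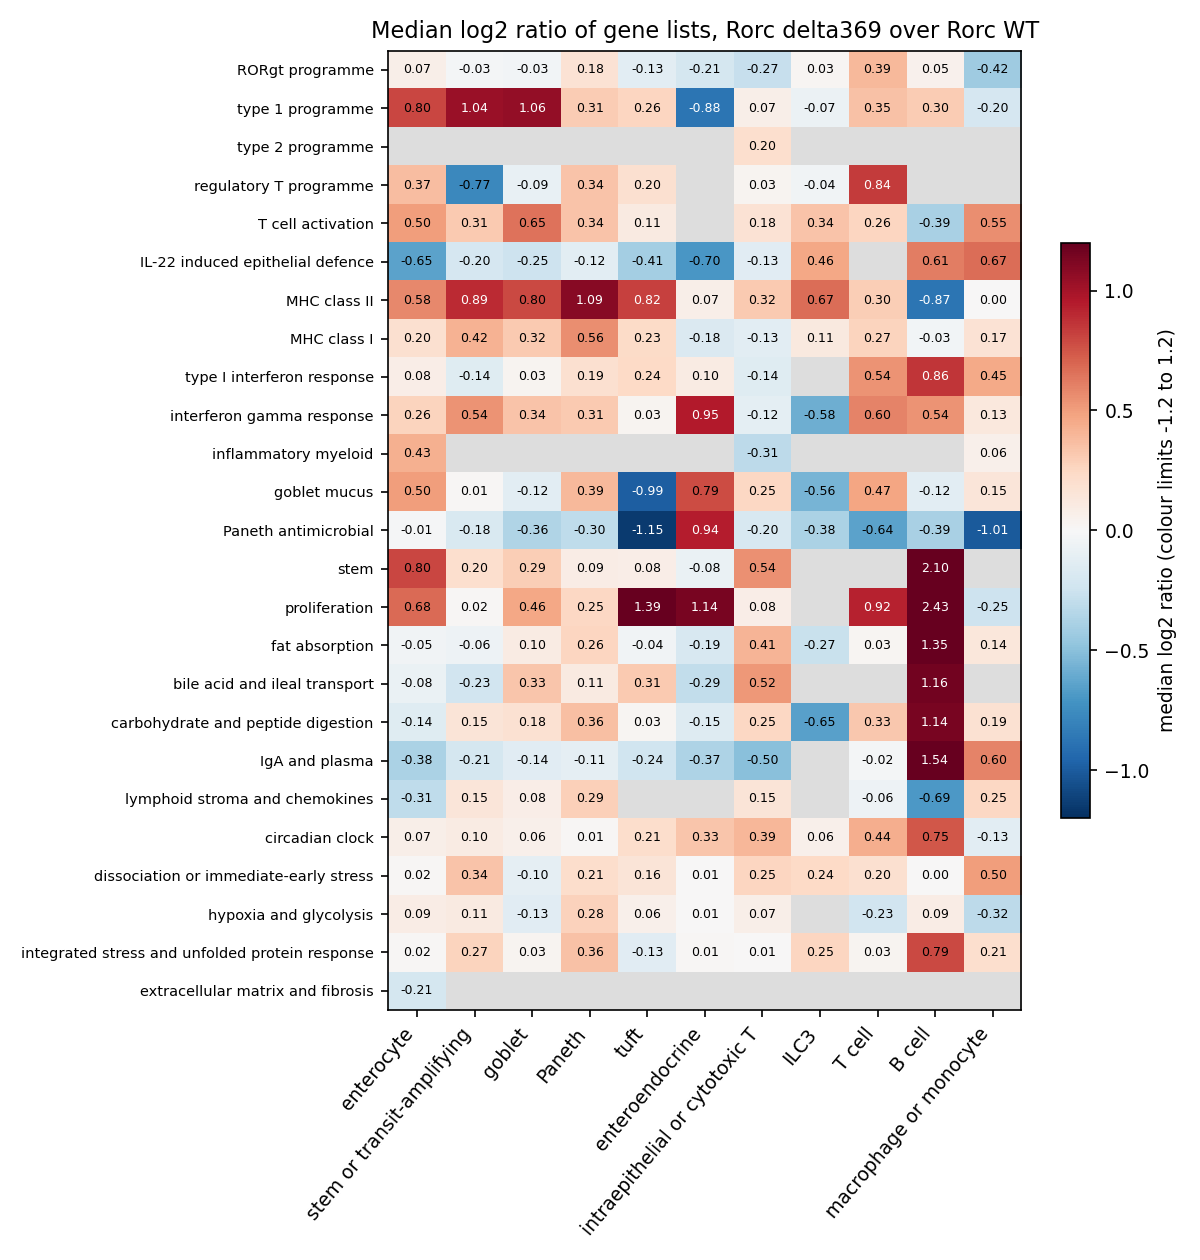
Median log2 ratio (Rorc delta369 over Rorc WT) of each gene list, as rows, in each cell class, as columns, from 1 library per genotype. The MHC class II list stood at 0.58 in enterocyte-like and 1.09 in Paneth-like cells, and the IL-22 list at -0.65 in enterocyte-like cells.

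The last comparison took in T cells and myeloid cells. Intraepithelial T-like cells of Rorc delta369 had more transcripts of Ifng, the cytokine that induces MHC class II, with 104 and 298 UMIs (2.21, 1.76 to 2.79). By the naming rule their highest ratios were those of Apol9a (2.43, 2.08 to 2.85), the NK receptor gene Klre1 (2.21, 2.04 to 2.39), the death receptor gene Fas (2.20), Mras (2.10) and Mcam (1.86). Their lowest were those of the chemokine gene Xcl1 (0.390, 0.372 to 0.408), Tmem273 (0.481), Klrb1a (0.554), the transcription factor gene Tcf7 (0.566) and Klra5 (0.574). The cluster led by Cd7 and Xcl1 was the largest of the class in Rorc WT (689 of 3329 cells) and held 390 of 4402 cells in Rorc delta369, where the largest cluster held 882. At the cluster shares of Rorc WT the ratio was 0.571 for Xcl1, 0.948 for Tcf7 and 2.20 for Ifng. The circadian clock list was higher for 12 of 15 members (median 0.39), with Nr1d1 at 2.02 and Npas2 at 2.05, and Dbp lower at 0.591. The RORγt programme list was lower for 9 of 14 members (-0.27), and Il17a counted 42 UMIs in 6 cells and 1 UMI (0.0184, 0.000455 to 0.108), while the unnamed T cell cluster held 25 Il17a UMIs in 7 cells and 92 in 9 cells.

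T-like cells, of which 126 of 211 lay in a cluster with Klf2 and Ms4a4b in Rorc WT and 47 of 77 in a cluster with Izumo1r and Ctla4 in Rorc delta369, had higher levels of regulatory T cell genes in Rorc delta369. All 11 measured members of that list were higher, at a median of 0.84, with Foxp3, the regulator of the lineage, at 3.63 (2.22 to 5.99) and Il10 at 6.21 (4.12 to 9.51). The median was -0.15 with the stricter filter, -0.14 with a mitochondrial limit of 50%, -0.12 with doublet calls kept and 0.43 at the cluster shares of Rorc WT. The naming rule gave Rbl2 (7.10, 3.61 to 14.8), Il10, Gzma, Fgl2 and Gzmb as the highest, and Xcl1 (101 of 121 UMIs in 1 cell), Srm (49 and 2 UMIs, 0.122, 0.0143 to 0.463), Nr4a1, Ccr7 (0.205) and Tesc as those ranked lowest, again with counts under 3 UMIs set to 3.

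Macrophage-like or monocyte-like cells of Rorc WT held a small cluster, with 13 cells against 1 in Rorc delta369, that carried all 686 UMIs of the class for Il22ra2, the soluble receptor that blocks IL-22, in 9 cells. Outside the class, an unnamed myeloid cluster closest to dendritic cells (27 and 13 cells) held 66 Il22ra2 UMIs in 9 cells and 204 in 5 cells, and over all filtered cells the gene counted 791 and 220 UMIs. The naming rule therefore gave Il22ra2 (686 and 1 UMIs, 0.00241, 0.0000609 to 0.0135), Cst7 (0.0429), Ccl17 (112 and 0 UMIs, at least 22.6-fold lower against a floor of 3 UMIs over the class), Fabp5 (0.0451, 0.00915 to 0.135) and Acod1 (78 and 1 UMIs, 0.0212, 0.000530 to 0.122) as the lowest. Without that cluster, Il22ra2 counted 0 and 0 UMIs, Ccl17 1 and 0, Cst7 6 and 3 (0.668, 0.108 to 3.13), Fabp5 5 and 3 (0.8015, 0.124 to 4.12) and Acod1 5 and 1 (0.267, 0.00565 to 2.39). The highest were Gcg (79 of 80 UMIs in 1 cell), the antiviral gene Rsad2 (12 and 65 UMIs, 8.95, 4.79 to 18.2), Ifit1bl1 (6.61, with 23 of 40 Rorc delta369 UMIs in 1 cell), Hspa1b (5.93) and Ear2 (4.55). Rsad2 UMIs lay for 84.6% in a cluster of 16 Rorc delta369 cells, and the type I interferon list had a median of 0.45, but -0.32 with clusters at resolution 0.6, -0.059 after thinning and -0.36 at the cluster shares of Rorc WT.

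Tuft-like cells of Rorc delta369 had higher ratios of Fabp6, Dmbt1 (3.07, with 96 of 174 UMIs in 1 cell), Hspa1b (2.86), Gsta1 (2.52) and Pafah1b2 (1.94). The lowest were the synaptic vesicle gene Rims2 (120 and 12 UMIs, 0.122, 0.0611 to 0.220), Sgk1 (0.467), Dnase1 (0.491), Gabra1 (0.514, but a log2 ratio of 0.17 after thinning) and Reg3b. In enteroendocrine-like cells the peptide hormone gene Cck counted 991 UMIs in 39 cells and 5330 UMIs in 52 cells (5.08, 4.74 to 5.44), beside Hspa1b (6.61, 3.13 to 16.1), Ly6m (4.34), Ada (3.85) and Pacrg (2.98). Single cells held 431 of the Rorc WT and 831 of the Rorc delta369 Cck UMIs, and the interval of Cck takes no account of this. They also held 38 of 80 Ada UMIs in Rorc WT, and 13 of 25 and 47 of 115 Ly6m UMIs. The lowest in enteroendocrine-like cells were Plb1 (0.169, 0.0992 to 0.273), Reg1 (44 of 50 Rorc WT UMIs in 1 cell), Slc51b, Tmigd1 (a log2 ratio of 0.39 after thinning) and Car4, up to 0.287. Of 129 Rorc WT cells, Plb1 was found in 12, Slc51b in 16 and Tmigd1 in 9. Plb1 was also among the leading genes of an enterocyte-like cluster, and mixed barcodes and free RNA were not excluded as the source of these transcripts.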

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

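The comparisons in this part were singled out by thresholds set after the values were seen, and no tests were planned for them.

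The goblet mucus list differed between epithelial classes, with a median log2 ratio of 0.50 in enterocyte-like cells and -0.99 in tuft-like cells, a difference of 1.49 that was not tested. Free RNA of goblet cells and mixed barcodes were not excluded as the source of these transcripts in either class. Among clusters without a name, 4 with at least 20 cells held a share at least 1.5 times larger in Rorc delta369, with intervals above 1. The threshold took in larger shares only, and 4 other clusters of that size held a share at least 1.5 times smaller, with intervals below 1 and ratios of 0.0303 and 0.0438 (B cell and plasma cell compartment), 0.277 (stromal) and 0.394 (myeloid). The T cell cluster next to the named T-like cells (161 and 347 cells) had a ratio of 1.76 (1.46 to 2.14). An epithelial cluster with 91 and 178 cells had a ratio of 1.6001 (1.24 to 2.08). Another epithelial cluster, with 50 and 140 cells, had a ratio of 2.29 (1.65 to 3.23). A small epithelial cluster with 1 cell in Rorc WT and 27 cells in Rorc delta369 had a ratio of 22.1 (3.64 to 904). These clusters were left without a name because they were mixed. The T cell cluster had leading genes of another class, the epithelial cluster with 91 and 178 cells carried markers of another compartment, with Gzma among its leading genes, and the other epithelial clusters carried markers of 2 classes, so barcodes that hold more than 1 cell were not excluded.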

How the results depend on the processing

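The tests with the Jchain and Igha cluster left out, with unnamed clusters or the unnamed T cell cluster added to the classes, with automatic doublet thresholds, with other denominators for ILC3-like cells, with macrophage-like cells without the Il22ra2 cluster, and with cluster shares within a class held at those of Rorc WT were added after the data were seen, and the other alternatives were planned. No paired analysis was possible because each genotype had 1 library and the labels pair no animals. Among the classes compared for genes, ILC3-like cells had the fewest UMIs (128563 and 79094), then the 77 T-like (129862) and 74 B-like cells (195320) of Rorc delta369. The ratio of Rorc in ILC3-like cells stayed within its counting interval under 12 of 12 alternatives (0.493 to 0.730), and the ratio of the share of ILC3-like cells under 8 of 8 (0.544 to 0.759). Of 88 values for the 6 leading list medians, 54 stayed within the interval, 32 moved outside it and 2 reversed. Of the 32, the 2 of the RORγt programme changed sign. Of 420 values for 33 other list medians, 316 stayed, 86 moved and 18 reversed, and of 650 values for 130 named genes, 531 stayed, 115 moved and 4 reversed. Unless stated, the cause was not tested for the values that follow.

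With the filter of 1000 UMIs and 10% mitochondrial UMIs, the share ratio was 0.993 for T-like, 1.37 for enteroendocrine-like, 1.21 for goblet-like, 1.198 for intraepithelial T-like and 0.591 for macrophage-like cells. Medians there were 0.41 for interferon-γ genes in stem-like and -0.63 (from 0.03) for the RORγt programme in ILC3-like cells. Reversed too were 0.30 for MHC class I and 0.22 for the IL-22 list in enteroendocrine-like cells. So were 0.016 for bile acid genes in enterocyte-like cells and -0.15 for regulatory T genes in T-like cells. With a mitochondrial limit of 50%, the share ratio was 0.964 for T-like and 1.255 for enterocyte-like cells, the median of MHC class II in stem-like cells 0.82, and reversed medians were 0.21 for MHC class I in enteroendocrine-like cells and -0.14 for regulatory T genes. With doublet calls kept, the share ratio of T-like cells was 0.919, medians were 0.80 for MHC class II in stem-like cells and -0.36 for the Paneth list, and reversed ones were 0.30 for MHC class I in enteroendocrine-like cells and -0.12 for regulatory T genes. At resolution 0.6, MHC class II in stem-like cells stood at 0.78, and reversed medians were 0.028 for MHC class I in enteroendocrine-like cells and -0.32 for type I interferon genes in macrophage-like cells. At resolution 1.6, the share ratio of intraepithelial T-like cells was 1.13, the Paneth list stood at -0.37 and MHC class I in enteroendocrine-like cells reversed to 0.22.

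The share ratio of B-like cells was 0.0302 without the Jchain and Igha cluster, and that of enterocyte-like cells 1.25 with all barcodes assigned. That of T-like cells was 0.932 both with unnamed clusters under their closest class and with the unnamed T cell cluster added. The added cluster was larger in Rorc delta369 (161 and 347 cells), while named T-like clusters took smaller shares of T-like and ILC-like cells. Their ratios were 0.183 (0.119 to 0.274) for the cluster with Klf2 and 0.425 (0.291 to 0.614) for that with Izumo1r. The value of 0.932 thus sums clusters that went opposite ways.

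Median-of-ratios scaling gave 0.52 for MHC class II and -0.71 for the IL-22 list in enterocyte-like cells and -0.48 for the Paneth list. Totals without the 20 most abundant genes gave 0.54, -0.69 and -0.50. Thinning to 1000 UMIs gave 0.70 for MHC class II in enterocyte-like cells and -0.070 for the Paneth list, and reversed the IL-22 list in enteroendocrine-like cells (0.11), fat absorption in enterocyte-like cells (0.030), type I interferon genes in macrophage-like cells (-0.059), Trgc2 in ILC3-like cells (0.056), Tmigd1 in enteroendocrine-like cells (0.39), Reg1 in goblet-like cells (0.10) and Gabra1 in tuft-like cells (0.17). With 5% of free RNA taken off, MHC class II stood at 0.70 in enterocyte-like and 1.03 in stem-like cells, and with 10% at 0.78 and 1.13, with interferon-γ genes in stem-like cells at 1.09. A list floor of 50 UMIs gave 0.68 for MHC class II in enterocyte-like cells, by leaving out the rare members, and a floor of 1 UMI gave 0.77 in stem-like cells, by adding them.

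Summed over all cells, medians were -0.29 for the RORγt programme (0.03 in ILC3-like cells) and -0.10 for MHC class II (reversed against enterocyte-like and stem-like cells). They were 0.18 for interferon-γ genes, -0.32 for the IL-22 list and -0.66 for the Paneth list. At the class shares of Rorc WT they were 0.26 for MHC class II, 0.25 for interferon-γ genes and -0.18 for the IL-22 list. At the cluster shares of Rorc WT within a class, MHC class II stood at 0.74 and the IL-22 list at -0.32 in enterocyte-like cells, and reversed medians were 0.12 for bile acid and 0.047 for carbohydrate genes in enterocyte-like cells, 0.021 for mucus genes in goblet-like cells and -0.36 for type I interferon genes in macrophage-like cells. Of the 20 genes ranked in ILC3-like cells, 2 were shared with the ranking after thinning and 0 with that at a floor of 100 UMIs, which few genes of this class reached. After thinning, 12 of the 20 genes in enterocyte-like cells were shared, and 36 of the 180 genes in the other 9 classes.

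On simulated sums, intervals covered the true ratio for 97.0%, 95.9% and 97.45% of genes at ILC3-like, enterocyte-like and B-like depths. Coverage with UMIs clumped in single cells was not simulated. Medians over genes with at least 30 UMIs were less exact in small classes. At B-like depth a true ratio of 0.25 gave a median log2 ratio of -1.385, not -2, with 83.3% of genes at least 0.5 from 0. At ILC3-like depth a ratio of 0.5 gave -1.201, not -1, with 81.8%.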

Other observations

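The tests of a general loss of lymphocytes, of a lower yield of lamina propria cells, of the place of the cut, of intraepithelial T cell RNA for the genes that were higher, of RNA of B cells and myeloid cells in stem-like cells, of scaling and depth, of a more distal piece, and of PPARα targets in enterocyte-like and goblet-like cells were chosen after the result was seen.

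Over all filtered cells, genes of supporting tissue and of inflamed myeloid cells were lower in Rorc delta369. The extracellular matrix and fibrosis list had 14 of 15 members lower (median log2 ratio -0.67), the inflammatory myeloid list 13 of 17 (-0.68), the lymphoid stroma and chemokine list 7 of 12 (-0.39) and the IgA and plasma list 10 of 11 (-0.44). The cells that make these transcripts were also fewer, with stromal-like cells at 2.27% and 1.03% of all cells, myeloid-like cells at 2.81% and 1.45%, and B-like or plasma-like cells at 11.4% and 0.788%. Proliferation genes were higher for 16 of 16 members (0.27) and stem cell genes for 9 of 11 (0.30). In tuft-like cells, proliferation genes were higher for 12 of 14 members (1.39), while the Paneth list was lower for 12 of 12 (-1.15). The Paneth list was also lower over the whole library, and free RNA and mixed barcodes were not excluded as its source in tuft-like cells.

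IL-22 UMIs were few. Over T-like and ILC-like cells, Il22 counted 35 UMIs in 16 Rorc WT cells (0.406%) and 14 UMIs in 9 Rorc delta369 cells (0.175%). The unnamed T cell cluster held 11 Il22 UMIs in 6 cells and 11 in 7 cells. Its genes with the highest ratios included the ligand gene Tnfsf8 (2 and 55 UMIs, 12.2, 3.23 to 103), and the T cell receptor gene Trgc1 was among those with the lowest (164 and 182 UMIs, 0.493).

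B-like cells made up 9.85% of the Rorc WT library and 0.439% of the Rorc delta369 library, and a lymphoid follicle in the Rorc WT piece, a general loss of lymphocytes, a lower yield of lamina propria cells or the place of the cut could each give such a gap. A loss of all lymphocytes is argued against by the ratio of 1.08 (1.03 to 1.13) for the share of intraepithelial T-like cells, but other cells of the lamina propria were fewer too, at 0.361 (0.199 to 0.634) for dendritic-like, 0.455 for stromal-like, 0.477 for macrophage-like, 0.574 for plasma-like and 0.579 for ILC3-like cells, and at 0.299 (0.227 to 0.389) for T-like cells alone but 0.932 with the unnamed T cell cluster, so their lower yield stays open as a part of the gap and is argued against as the whole of it, since B-like cells stood at 0.0445 (0.0347 to 0.0563). For a follicle, 7 measured genes of follicle epithelium had a median log2 ratio of -0.052 (-0.19 to 0.07) over all epithelial cells, which met the bound written against it beforehand, but 3 were higher and 4 lower, so by a rule with limits of 0.25 and 1 in 3 set afterwards the median was taken to decide nothing. Gp2 counted 11 and 2 UMIs and Spib 1131 and 884, and a high baseline was not the reason, since 2 of the 7 stood at 5 CPM or more in Rorc delta369 enterocyte-like cells. Counts of other cells also went with a follicle in the Rorc WT piece, but were not part of that test. The unnamed cluster closest to germinal-centre B cells held 81 and 3 cells, and the T-like cluster with Klf2 held 126 and 30. With 1 library per genotype, a follicle, the place of the cut and the genotype cannot be told apart.

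MHC class II genes were higher in enterocyte-like and stem-like cells (medians 0.58 and 0.89), for which RNA of other cells and scaling or depth were weighed, with genotype, animal and place of the piece untested as the source of a higher level in the cells themselves. RNA of B cells and myeloid cells is argued against by the median of -0.85 (-1.44 to -0.55) of other genes of such cells in enterocyte-like cells, and more weakly in stem-like cells by one of -0.16 (-0.85 to 0.21) over 6 genes, below that of MHC class II there. The bound for stem-like cells, written afterwards, asked only for an interval below that of MHC class II. The stricter bound used for enterocyte-like cells, an interval below 0, was not met in stem-like cells. In enterocyte-like cells, scaling or depth is argued against by a lowest median of 0.52 over 5 settings. RNA of intraepithelial T cells was more frequent in both classes, with 13 of 13 genes higher, but in each 0 of the 7 MHC class II genes that were higher had a still higher level in intraepithelial T-like cells (H2-Aa 87.6 CPM there against 1490 and 628 CPM). For the other 3 in enterocyte-like cells, H2-DMb2, H2-Oa and H2-Ob, all under 1 CPM in Rorc delta369, the level was higher in intraepithelial T-like cells. These 3 genes were lower in Rorc delta369 and are best known from B cells, which were fewer there. For them, RNA of B cells, RNA of intraepithelial T cells and transcripts of the enterocyte-like cells themselves cannot be told apart.

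For higher Fabp6 and lower Hmgcs2 in epithelial classes, a more distal piece and lower PPARα-driven transcription were weighed, while no test addressed Fabp6 alone, and the genotype, the animal and its feeding state stay open as untested. Free RNA stays open as well for Fabp6 outside enterocyte-like cells, since its ratio was 5.22 in intraepithelial T-like cells. It also stays open for Hmgcs2 in enterocyte-like cells, since intraepithelial T-like cells of Rorc WT held Hmgcs2 at much the same level (ratio 0.0539 there). In enterocyte-like cells, a more distal piece is argued against by a difference of -0.34 between the medians of distal genes (-0.25, 5 of 6 lower) and proximal genes (0.09). This rests on 6 distal genes and was not repeated at the cluster shares of Rorc WT, where the bile acid and ileal transport list reversed. In goblet-like cells the difference was 0.23, with distal genes higher for 6 of 6 (0.35, 0.19 to 0.52) and proximal genes for 10 of 10 (0.12), and a more distal piece and no difference in place cannot be told apart there. In stem-like cells, other PPARα targets were lower for 12 of 15 members, at a median of -0.54 (-0.60 to -0.42), so lower PPARα-driven transcription is a candidate explanation for Hmgcs2 there. In enterocyte-like cells the median of 0.033 met the bound written against it, but lay near 0 over members that went both ways (9 higher, 7 lower) and was taken to decide nothing, in goblet-like cells that of -0.21 (4 higher, 11 lower) lay between the bounds, and in these classes lower PPARα-driven transcription and no difference in it cannot be told apart.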
